A study of Synechocystis sp. PCC 6803 with 8 samples.

How the data were processed

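The samples were 8 total RNA extracts, 4 groups of 2, from cultures grown at 30 °C under 50 µmol photons m-2 s-1, diluted to an optical density of 0.8, and harvested at 17.5 h or 29.5 h, as the labels' protocols state. RNA was labelled directly with Cy3 without cDNA synthesis, in aliquots of 2 µg, per the labels' protocols. Fluorescence intensity was extracted with Agilent Feature Extraction 10.7.3.1, per the file headers, and the processed signal, median signal and background median were deposited on a linear intensity scale. The authors' value table is on a log2 scale, and limma is named in the submitters' processing notes. Its 8 columns had medians from 9.26 to 9.32 and correlated at 0.999 with normexp-corrected, quantile-normalized values of the same array, while its exact steps and centring are not given in the sources used here. The flags for background, saturation and outliers are other values deposited with each spot, per the file headers.

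Here R 4.3.3 and limma 3.58.1 were used. The 1319 control spots were left out, 4 outlier spots were set to missing, and no non-control spot was saturated. The log2 processed signal minus each array's 75th percentile was used. A probe was tested if well above background on at least 2 arrays, which left 43890 of 61015 probes, and 5926 were well above background on all arrays. Each probe was spotted once, so a feature is a probe. Group means of all 8 arrays were fitted together with lmFit and eBayes, with 5 contrasts, and a call is a Benjamini-Hochberg adjusted p under 0.05 within the contrast. A probe well above background on only some arrays of a group kept its own values. For a probe well above background on no array of a group, the fold is a bound. It sets the bright group's mean against the dim group's mean of, per array, the higher of the lowest signal well above background and the probe's own signal. The limma p given beside a bound belongs to the fitted change, with dim values as measured, and does not test the bound. Two-sided camera with a preset correlation of 0.01 was run on the probe groups, with Benjamini-Hochberg adjustment over the 5 groups, beside camera with an estimated correlation and fry. Rank correlations used 100000 permutations. Probe groups were also compared over probes well above background on all arrays, with adjustment over the 4 groups that kept enough probes, and bounds of numbered probes were repeated under other scalings.

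The 22 gene lists with 289 members, and the check of rpaA and its neighbour, were fixed before the data were examined. None could be applied, because the numbered probes could not be joined to gene names here, and the reference table of ASM28445v1 shares no identifier with them. The groups CRISPR1, CRISPR2, CRISPR3, LEADER1 and LEADER2 were formed from probe names after the data were seen. The named probes follow a rule fixed beforehand: the 3 highest and 3 lowest called features of each non-coding class, with each probe group taken as a class, and the text gives a selection or summary of them. Some single probes that the rule names are not reported here. The numbered probes named are those with the largest called changes between phases, at most 2 in each direction, and were chosen after their values were seen. The background setting named for normexp used the median signal, because the files hold no mean signal column.

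The fit was tested on simulated data with 200 changed numbered probes among 43890, and with the CRISPR3 probes shifted as well. Each probe was given the same spread on all 8 arrays. In the data replicates differed more in ΔrpaA dark than in WT light (median absolute log2 difference 1.24 against 0.12 after scaling). That difference may include an offset from the scaling, while the SD of the log2 differences, which an offset does not change, was 0.88 against 0.22. The shares called may thus not hold for the data. For ΔrpaA against WT in light, 81.8% of changes of 4 on the log2 scale were called, 5.97% of changes of 2 and 0% of changes of 1, with 1 of 43653 unchanged probes called. For the interaction, 4.55% of changes of 4 were called.

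All 8 arrays lay on 1 slide with 1 scan, so no slide block could be fitted. WT arrays lay in one row of the slide and ΔrpaA arrays in the other, so slide row and genotype cannot be told apart. The alternatives covered background correction, normalization, scaling, filters, the authors' value table, the arrays in the fit, a replicate block, the variance model, the threshold and each array left out.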

Results

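Total RNA of the cyanobacterium Synechocystis sp. PCC 6803 was measured on 8 one-colour microarrays. Wild type (WT) and a strain lacking rpaA (ΔrpaA) were each sampled at 5.5 h after the onset of light and at 5.5 h after the onset of dark in a cycle with phases of 12 h. RpaA is known as the output response regulator of the circadian clock in cyanobacteria. Each of the 4 groups held 2 arrays, which the series' design text describes as independent experiments, and this number limits the precision. The array carried 61015 non-control probes, of which 149 had names that point to CRISPR arrays or their leaders and 60866 had numbers only. CRISPR arrays hold repeats and spacers that are transcribed and processed into guide RNAs, and the leader lies upstream of the first repeat. The files used here pair no numbered probe with a gene, so rpaA itself could not be checked as the targeted gene and values are given for the named regions. Coordinates of the probes were not used here.

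The share of probes well above background was 61.9% and 67.2% on the WT light arrays and 69.1% and 74.2% on the ΔrpaA light arrays. It was 30.5% and 34.3% on the WT dark arrays, and 10.6% and 28.1% on the ΔrpaA dark arrays. From light to dark the share dropped by 42.2 percentage points on average (exact permutation test within genotypes, two-sided p = 0.0556, the smallest that the 36 splits allow, adjusted p = 0.0833 over 6 measures, n = 4 per phase), and each dark array lay below each light array. The 75th percentile of signal was 10.2-fold lower in dark, while the median of the 17 CRISPR1 probes was 1.31-fold lower (exact permutation p = 0.111, adjusted p = 0.133, n = 4 per phase). The first ΔrpaA dark array had its 75th percentile at 54.2 units, close to its lowest value of 48.7 units.

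**Figure D1:**
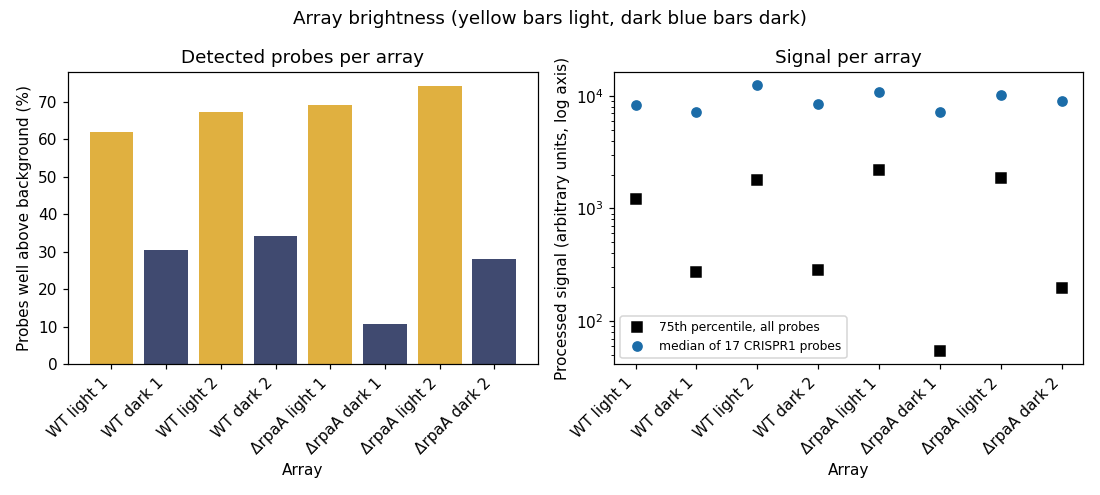
Left, the percentage of probes well above background on each of the 8 arrays, in yellow for light and dark blue for dark. Right, on a log axis, the 75th percentile of processed signal (squares) and the median of 17 CRISPR1 probes (circles) in arbitrary units. The squares range from 54.2 to 2176 units and the circles from 7128 to 12430 units.

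The first comparison asked how loss of rpaA changes transcripts in light. CRISPR3 and CRISPR2 signal was far lower in ΔrpaA, and CRISPR1 signal differed far less. WT and ΔrpaA arrays lay in different rows of the slide, so slide row and genotype cannot be told apart in either genotype comparison. Of the 37 tested CRISPR3 probes, 21 passed as lower and none as higher, and the median log2 change was -5.51. Of the 41 tested CRISPR2 probes, 5 passed as lower and none as higher, with a median log2 change of -3.44. The highest single changes were -0.93 for CRISPR3 and -0.83 for CRISPR2, so every tested probe of both groups was lower, called or not. With scaling on probes detected on all arrays 31 CRISPR3 and 29 CRISPR2 probes passed as lower. With probes well above background on no array of a group set at their bound, the medians were -4.71 for CRISPR3 and -2.68 for CRISPR2. Adjusted over the list alone, 36 CRISPR3 and 38 CRISPR2 probes passed as lower. The 17 tested CRISPR1 probes had a median of -0.48, and none passed the threshold. Both falls exceeded that of the other probes by camera (limma, adjusted p = 7.8e-156 for CRISPR3 and 9.5e-128 for CRISPR2, with a preset correlation of 0.01). Both calls held with an estimated correlation, where the adjusted p = 0.0123 for each. CRISPR1 had a camera adjusted p = 0.00011, which was lost with an estimated correlation (adjusted p = 0.348). LEADER1, with 4 probes, had a median of -0.59 and LEADER2, with 2 tested probes, had -0.81, and no leader probe passed. Their camera adjusted p values were 0.010 and 0.0189, and with an estimated correlation the adjusted p = 0.0975 and 0.193. Over probes well above background on all arrays, CRISPR3 lay at -2.31 and CRISPR2 at -2.65 relative to the median of such probes. There camera with an estimated correlation gave an adjusted p = 0.0226 for each. This leaves out the probes that were dim in ΔrpaA, and among the rest CRISPR3 did not fall further than CRISPR2.

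Single probes showed the size of the loss. R_CRISPR3-24 had mean normalized log2 values of 3.17 in WT and -5.46 in ΔrpaA, where it was not well above background on either array, so that WT was at least 82.2-fold brighter (limma adjusted p = 0.00464). R_CRISPR3-27 was at least 58.2-fold brighter in WT (limma adjusted p = 0.00464), and R_CRISPR3-21 at least 62.0-fold (limma adjusted p = 0.0280). R_CRISPR2-15 was at least 38.0-fold brighter in WT (limma adjusted p = 0.00464). R_CRISPR2-24 was at least 7.47-fold brighter (limma adjusted p = 0.0350).

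The loss in CRISPR3 differed along the probe numbers. Probes 1 to 9 all stayed well above background on the 4 ΔrpaA arrays, with a median log2 change of -2.00 in light and none called. Probes 10 to 38 had a median of -6.20, or -5.34 with dim probes at their bound, and 21 of the 28 tested passed as lower. Of these 28 probes 15 were well above background on no ΔrpaA array. The split at probe 9 was chosen after the values were seen. Over the 15 CRISPR3 probes well above background on all 8 arrays, Spearman's rho of the change with probe number was -0.72 (permutation p = 0.00353), across probes, which are not independent replicates. Over all 37 tested probes rho was -0.61 and Pearson's r was -0.64 (permutation adjusted p = 0.000240 for rho over 4 relations), and with dim probes at their bound rho was -0.34 (permutation p = 0.0397). For CRISPR2 rho was -0.27 in light (permutation adjusted p = 0.122). The sign for CRISPR2 turned with dim probes at their bound, where rho was 0.19 in light and 0.46 in dark (permutation p = 0.238 and 0.0025), and over the 13 probes well above background on all arrays, where rho was 0.19 and 0.47 (permutation p = 0.540 and 0.112). In all, 37 probes passed in light, 3 higher and 34 lower, of which 26 lower ones were CRISPR2 or CRISPR3 probes. That count rose to 353 when each array was scaled on the probes detected on all arrays, with 208 higher and 145 lower, and fell to 0 without any 1 of the WT light, WT dark or ΔrpaA light arrays. It was 2065 without either ΔrpaA dark array.

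**Figure D2:**
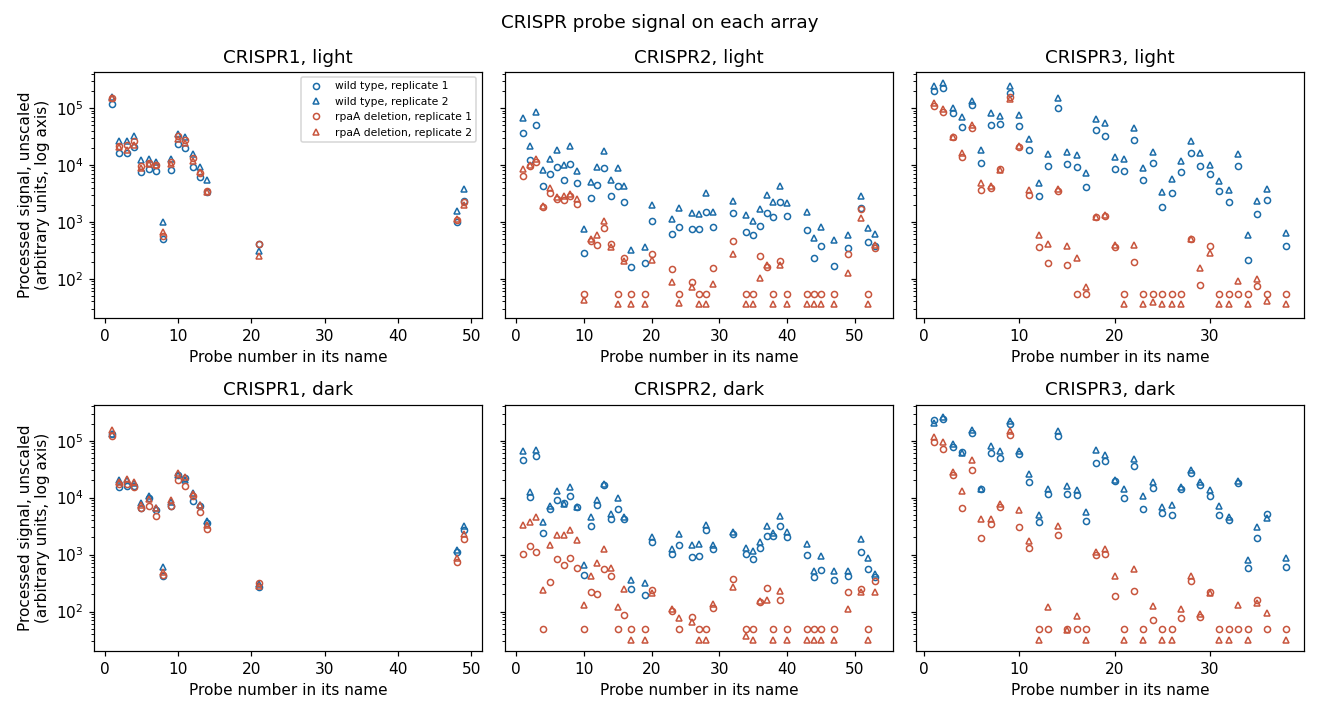
Unscaled processed signal (log axis, arbitrary units) of each tested CRISPR probe against the number in its name, for light (top) and dark (bottom), with WT in blue, ΔrpaA in red, circles for replicate 1 and triangles for replicate 2. CRISPR1 points of both strains overlap, while CRISPR2 and CRISPR3 points of ΔrpaA lie below WT and many sit at the lowest value of their array.

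In the dark the same named regions were lower in ΔrpaA relative to other probes. Under the scaling used here the median log2 change of all tested probes was 1.09 in this comparison, so shifts are given relative to it. CRISPR3 lay at -5.78 and CRISPR2 at -3.29 relative to that median, and CRISPR1 lay at 0.26. Not taken relative to it, the medians were -4.69, -2.20 and 1.35. At their bounds, the CRISPR3 and CRISPR2 medians were -3.45 and -1.45. By camera CRISPR3 and CRISPR2 were lower (limma, adjusted p = 7.0e-53 and 1.9e-43), and both calls were lost with an estimated correlation (adjusted p = 0.0797 for each). CRISPR1 was called higher by camera (adjusted p = 0.0101) but not with an estimated correlation (adjusted p = 0.505). LEADER1 lay at -1.64 (camera adjusted p = 0.0496, and adjusted p = 0.185 with an estimated correlation), and LEADER2 at -1.17 (camera adjusted p = 0.322). Over probes well above background on all arrays, CRISPR3 lay at -2.55 and CRISPR2 at -2.61 relative to the median of such probes. There camera with an estimated correlation gave an adjusted p = 0.0675 for each. Only R_CRISPR3-24 and R_CRISPR3-33 passed singly, with WT at least 31.0-fold and at least 35.1-fold brighter (limma adjusted p = 0.0479 for both). Both calls were lost with a replicate block and without the filter. Adjusted over the list alone, 31 CRISPR3 and 33 CRISPR2 probes passed as lower, and with scaling on probes detected on all arrays 31 and 34 did. Of all tested probes, 2 passed, both lower, against 2254 with scaling on probes detected on all arrays (632 higher and 1622 lower) and 8012 at an unadjusted p under 0.05. The count was 9017 without the first ΔrpaA dark array, 35018 without the second, and 0 without any other array.

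Changes with genotype in light and dark shared no arrays. Over the 15 CRISPR3 probes well above background on all arrays, the changes correlated with Pearson's r = 0.95 and Spearman's rho = 0.93 (permutation adjusted p = 2e-05 and 4e-05 over 2 relations). Over the 13 such CRISPR2 probes r was 0.74 and rho 0.80 (permutation adjusted p = 0.00388 and 0.0015), again across probes, which are not independent replicates. Over the same probes the mean CRISPR3 signal minus mean CRISPR1 signal within each array, which is free of scaling, was 3.21 ± 0.19 on the log2 scale in WT and 0.25 ± 0.16 in ΔrpaA (SD, n = 4 arrays each). For CRISPR2 the values were 0.02 ± 0.16 and -2.43 ± 0.63 (SD, n = 4 arrays each). The exact permutation test within phases gave p = 0.0556 for both (adjusted p = 0.111 over 6 tests), the smallest p that the 36 splits allow, and all 4 ΔrpaA arrays lay below all 4 WT arrays.

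The dark against light comparison in WT asked which transcripts differ between the phases. Dark samples were harvested at 17.5 h and light samples at 29.5 h. Phase and harvest time therefore cannot be told apart in either phase comparison. Relative to the median of all tested probes (-0.31), CRISPR1 was 2.50, CRISPR2 3.01 and CRISPR3 2.97 higher in dark. Of these probes 15 of 17, 36 of 41 and 36 of 37 passed as higher under the scaling used here, although CRISPR1 turned to lower values without scaling. With scaling on probes detected on all arrays 0 of 17, 10 of 41 and 14 of 37 passed as higher. By camera all 3 groups were higher (limma, adjusted p = 2.2e-07, 5.1e-15 and 7.1e-15). These camera calls were lost with an estimated correlation (adjusted p = 0.387 for each). Over probes well above background on all arrays, CRISPR1 lay 0.50, CRISPR2 0.64 and CRISPR3 0.73 above the median of such probes. There the camera adjusted p = 0.0928, 0.0430 and 0.0430, and with an estimated correlation the adjusted p = 0.653 for each. Without scaling, CRISPR1 signal was -0.22 in dark against light, CRISPR2 0.26 and CRISPR3 0.25, while 37379 numbered probes detected in light had a median of -3.01. LEADER1 and LEADER2 had unscaled medians of -2.20 and -4.08, and against all tested probes their camera adjusted p = 0.494 and 0.204. R_LEADER2-2 fell by 1.94 on the log2 scale (SE 0.52, limma adjusted p = 0.0265). In all, 13639 probes passed, 6394 higher and 7245 lower (46.9% higher). With scaling on probes detected on all arrays 29806 passed, of which 8.60% were higher. The count was 32956 without either ΔrpaA dark array and between 2072 and 7980 without any other array. Under the scaling used here the probe SYN-CR-76-20330 was at least 1272-fold brighter in dark and SYN-CR-76-29858 at least 957-fold (limma adjusted p = 0.000827 for both). These bounds were 426-fold and 321-fold with scaling on probes detected on all arrays, and 239.9-fold and 180.6-fold without scaling. SYN-CR-76-33471 and SYN-CR-76-46594 were at least 37.8-fold and 33.3-fold brighter in light (limma adjusted p = 0.000827 for both), and the bounds were higher, at 113-fold and 99.2-fold with scaling on probes detected on all arrays and at 200.3-fold and 176-fold without scaling.

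In ΔrpaA CRISPR1 was 3.53 higher in dark relative to the median of all tested probes (0.41) under the scaling used here. The camera adjusted p for this rise was 3.7e-10, and with an estimated correlation the adjusted p = 0.277. Of its probes 17 of 17 passed as higher. CRISPR1 turned to lower values without scaling. Of the CRISPR2 probes 21 of 41, and of the CRISPR3 probes 15 of 37, were not well above background in either phase and have no measured change. Without them, and with other dim probes at their bound, the median log2 changes were 3.47 for CRISPR2 and 3.87 for CRISPR3, against 3.95 for CRISPR1. Over probes well above background on all arrays, CRISPR1 lay 1.30, CRISPR2 0.50 and CRISPR3 1.41 above the median of such probes (camera adjusted p = 0.0146, 0.0804 and 0.0146, and adjusted p = 0.537 for each with an estimated correlation). Without scaling, CRISPR1 was -0.34 in dark, the 17 CRISPR2 probes detected in light -0.99, the 18 such CRISPR3 probes -0.37, LEADER1 -4.08 and LEADER2 -5.23, and 41848 numbered probes had a median of -3.97. These values rest in part on the first ΔrpaA dark array, where the LEADER2 median lay at the lowest value of the array. Without that array they were -0.16 for CRISPR1, -0.35 for CRISPR2, -0.11 for CRISPR3, -2.66 for LEADER1, -3.61 for LEADER2 and -3.75 for the numbered probes. Without the second they were -0.47, -1.76, -0.55, -5.46, -6.86 and -4.09. On the first ΔrpaA dark array 74.3% of all probes lay at its lowest value, and on the second 53.0%. The medians of the numbered probes can be limited by these lowest values and may understate the fall. Against all tested probes the leaders had camera adjusted p = 0.757 and 0.194. R_LEADER1-4 had a log2 change of 2.44 (SE 0.61, limma adjusted p = 0.0240), and without scaling its change was -1.85. With scaling on probes detected on all arrays 0 leader probes passed as higher, and 3 of 4 LEADER1 and 2 of 2 LEADER2 probes passed as lower. In all, 11063 probes passed, 8567 higher and 2496 lower (77.4% higher), against 30900 with 8.80% higher when scaled on probes detected on all arrays. Without the first ΔrpaA dark array 28153 passed, without the second 33293, and between 1668 and 7358 without any other array. SYN-CR-76-20330 and SYN-CR-76-29858 were at least 4647-fold and at least 2951-fold brighter in dark under the scaling used here (limma adjusted p = 0.000341 for both). The bounds were 943-fold and 599-fold with scaling on probes detected on all arrays, and 238-fold and 151-fold without scaling. SYN-CR-76-31297 and SYN-CR-76-981 were at least 27.9-fold and 27.3-fold brighter in light (limma adjusted p = 0.00129 and 0.00125). Their bounds were 137-fold and 135-fold with scaling on probes detected on all arrays, and 543-fold and 532-fold without scaling.

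Leader signal within each array was lower in dark relative to CRISPR1, a group that fell less than the numbered probes without scaling. Mean LEADER1 minus mean CRISPR1 was 1.23 ± 0.11 in light and -1.32 ± 1.23 in dark (log2, SD, n = 4 arrays each), with the first ΔrpaA dark array at -3.12 and the other 3 between -1.12 and -0.43. For LEADER2 it was -0.32 ± 0.28 in light (SD, n = 4 arrays). In dark LEADER2 lay at the lowest value of the first ΔrpaA array, which gives no measured level there, and between -4.12 and -3.87 on the other 3 arrays. The exact permutation test within genotypes gave p = 0.0556 for both (adjusted p = 0.111 over 8 tests), the smallest p allowed, with no overlap between the light and dark arrays. Across the 5926 probes well above background on all arrays the dark changes of WT and ΔrpaA, which share no arrays, correlated with Pearson's r = 0.83 and Spearman's rho = 0.81. Of the calls among them, 2697 probes were higher in both strains against 2038 for independent lists, 30 were lower in both against 1.31, and 0 had opposite signs under the scaling used here. With scaling on these probes 953 were higher in both against 379, 884 were lower in both against 259, and 3 had opposite signs.

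The interaction asked whether the phase change differs between strains. No probe passed (limma, 3679 at an unadjusted p under 0.05), under the scaling used here and with scaling on probes detected on all arrays. The count was 6119 without the first ΔrpaA dark array, 31870 without the second, and 0 without any other array. Other settings called probes with no common direction, 203 higher and 631 lower with quantile normalization, 835 and 722 with normexp, 272 and 19 with trend and robust variance, 52 and 0 with the filter on all arrays, and 145 and 3034 without scaling. Relative to the median of all tested probes (0.99), CRISPR1 was 0.88, CRISPR2 0.34 and CRISPR3 0.30 higher, but 21 of the 41 CRISPR2 and 15 of the 37 CRISPR3 probes have no measured change in ΔrpaA, so the values of these groups are set largely by the lowest values of the arrays. By camera the adjusted p was 0.00015 for CRISPR1, 0.0362 for CRISPR2 and 0.0292 for CRISPR3, and with an estimated correlation the adjusted p = 0.780 for each. LEADER1 lay at -0.90 and LEADER2 at -0.27 (camera adjusted p = 0.673 and 0.822). Over probes well above background on all arrays, CRISPR1 lay at 0.83, CRISPR2 at -0.42 and CRISPR3 at 0.38 (camera adjusted p = 0.00332, 0.429 and 0.225, and adjusted p = 0.776 for each with an estimated correlation). The direction for CRISPR2 also turned with quantile normalization and that for CRISPR3 with the authors' value table. Without scaling, the CRISPR1 median changed by -0.22 in WT and -0.34 in ΔrpaA, so its shift here is relative to the other probes.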

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

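All tests of explanations in this part were chosen after the results were seen. The phase change of 3 probe groups differed between strains by the interaction contrast under camera: CRISPR1 by 0.88, CRISPR2 by 0.34 and CRISPR3 by 0.30 on the log2 scale, relative to all tested probes. The CRISPR2 and CRISPR3 values are set largely by the lowest values of the arrays, since 21 of 41 and 15 of 37 probes have no measured change in ΔrpaA. Over probes well above background on all arrays they were -0.42 and 0.38 (camera adjusted p = 0.429 and 0.225), and CRISPR1 was 0.83 (camera adjusted p = 0.00332). With an estimated correlation none of the 3 differences passed (adjusted p = 0.780 for each over all tested probes). Without scaling, the CRISPR1 median changed by -0.22 in WT and -0.34 in ΔrpaA from light to dark. The numbered probes detected in light changed by -3.01 and -3.97. The CRISPR1 difference is thus relative to other probes that fell further in ΔrpaA, and not a rise of its own unscaled signal.

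The first pattern is the lower CRISPR2 and CRISPR3 signal in ΔrpaA, tested on CRISPR3. Lower overall signal of the ΔrpaA arrays is argued against by CRISPR3 minus CRISPR1 signal within each array, which changed by -2.96 on the log2 scale from WT to ΔrpaA over probes well above background on all arrays, beyond the SDs over arrays (0.19 and 0.16). Loss of the whole CRISPR3 array from the DNA of all cells cannot be decided. On all ΔrpaA arrays 15 CRISPR3 probes were well above background, but without probe sequences signal from other RNA was not excluded. An equal fall over all CRISPR3 probes cannot be decided either. Over these 15 probes rho with probe number was -0.72, but signal from other RNA on some of them could give unequal falls. Loss of the later repeats from the DNA cannot be told apart from lower transcript levels, since 6 of 28 later probes stayed well above background on all ΔrpaA arrays but probe sequences and DNA were not used here. Slide row, which cannot be told apart from genotype, and the loss of rpaA itself stay open and untested.

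The second pattern is the dimmer dark arrays. In WT the unscaled CRISPR1 median lay 3.19 on the log2 scale above random sets of 17 numbered probes matched on brightness in light. Of these 10000 sets, 0 were as high. Matched on mean brightness in light and dark, the CRISPR1 median lay 2.02 above such sets, and 22 of 10000 sets were as high. In ΔrpaA the differences were 4.81 and 2.62. These gaps cannot decide on a single lower labelling or hybridisation yield for all RNA. More CRISPR1 RNA in dark on top of such a yield would give the same gaps. The CRISPR1 changes in WT lay close together (SD 0.20, against 1.89 for numbered probes of that brightness range). The 17 probes may thus not act as independent draws. A lower yield stays open. A lower share of messenger RNA in equal amounts of total RNA, and phase itself, also stay open and untested.

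The third pattern is the first ΔrpaA dark array, the dimmest of the 8. Its CRISPR1 median against the second array lay 0.60 above random sets matched on brightness on the second array, and 73 of 10000 sets were as high, but matched on mean brightness it lay 0.26 above and 1162 were as high. With sets drawn from the whole brightness range, tried first, 1 was as high, so the outcome depends on the matching. A lower yield for the whole array and a difference in its RNA cannot be told apart, since CRISPR1 fell by 0.27, LEADER1 by 2.76 and the numbered probes by 1.64 but these groups differ in brightness. Only 10.6% of probes were well above background on the first array, so the fall of the numbered probes can be limited by its lowest value. No biological explanation was tested for this difference between replicates.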

How the results depend on the processing

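The unscaled setting, its values without each ΔrpaA dark array, and the within-array differences and correlations over probes well above background on all arrays, were chosen after seeing the data. The shifts of CRISPR2 and CRISPR3 with genotype kept their direction under every setting run, and their call except with an estimated correlation in dark, where the shifts were -3.29 and -5.78 (adjusted p = 0.0797 for each). Counts of calls did not hold. In the order ΔrpaA against WT in light, in dark, dark against light in WT, in ΔrpaA, and interaction, the counts were 37, 2, 13639, 11063 and 0. They were 1337, 4528, 29168, 31675 and 1557 with normexp, 523, 3327, 23140, 24043 and 834 with quantile normalization, and 617, 2040, 20908, 17178 and 841 with median scaling. They were 353, 2254, 29806, 30900 and 0 with scaling on probes detected on all arrays, and 588, 4095, 23861, 28583 and 591 with normexp and quantile normalization. The authors' value table gave 584, 4165, 24194, 28790 and 598. No filter gave 36, 0, 10811, 26881 and 0, and a filter on all arrays gave 17, 721, 4041, 5050 and 52. Trend and robust variance gave 349, 2667, 16422, 14535 and 291, and no scaling gave 743, 6573, 35068, 40936 and 3179. With only the arrays compared, the first 4 were 3776, 38, 31720 and 643. Under the main scaling the threshold of 1 on the log2 change altered no count. Under other settings it did: in dark it cut 4165 to 3031 with the authors' value table and 4528 to 2348 with normexp.

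Leaving out each array in turn gave counts from 0 to 2065 in light, 0 to 35018 in dark, 2072 to 32956 in WT, 1668 to 33293 in ΔrpaA and 0 to 31870 for the interaction, and a lone array was assumed to vary like the other groups. The highest counts came without a ΔrpaA dark array, whose pair differed most (median absolute log2 difference 1.24, against 0.12 for WT light). With the replicate number as a block the counts were 49, 0, 13283, 10492 and 0. The numbers were not shown to pair the samples: deviations correlated between -0.35 and 0.28.

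The CRISPR2 interaction shift reversed to -0.28 with quantile normalization, -0.15 with normexp and quantile normalization, -0.033 with the authors' value table and -0.42 with the filter on all arrays. The CRISPR3 interaction shift reversed to -0.53, -0.24 and -0.0071 with normexp and quantile normalization, the authors' value table and no filter, and the first of these passed camera in the opposite direction (adjusted p = 0.00504). Without scaling, the dark change of R_CRISPR1-6 in WT was -0.0011, and in ΔrpaA those of R_CRISPR1-49, R_CRISPR1-3, R_CRISPR1-21 and R_LEADER1-4 were -0.025, -0.070, -0.094 and -1.85. Apart from the scaling itself, the cause was not tested. Averaging probes of a gene, a slide block, and the rpaA and gene list results were not run. Signal over background limits the dark comparisons, where 74.3% of probes on the first ΔrpaA dark array lay at its lowest value.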

Other observations

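CRISPR1 probes were seen at the ends of the numbering. Of the 33 probes numbered 15 to 47, 32 were not well above background on any of the 8 arrays, and number 21 was the exception. All 16 probes outside that range were well above background on all 8 arrays.

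In total 48 probes were well above background on all 4 WT arrays and on no ΔrpaA array, and 31 of them were CRISPR2 (17) or CRISPR3 (14) probes. Another 4 probes, none of them named, showed the reverse. Their sum of 52 was not the highest. Of the 18 splits balanced for phase 2 gave a sum as large, and the highest other split gave 59.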
